A study of Mus musculus with 23 samples.

How the data were processed

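RNA from the hippocampus of 23 mice was measured on an nCounter metabolic pathways panel, an assay in which colour-coded probes hybridised to each transcript are counted without amplification. The labels gave 5 groups. They were wild-type mice on vehicle (4 mice), AD mice on vehicle (5), ADPolB mice on vehicle (4), AD mice given urolithin A (5) and ADPolB mice given urolithin A (5). Sex, age, dose and duration were copied from the labels, and each sample was taken as 1 mouse, since no label linked samples to each other.

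The deposited table held log2 of normalized nCounter counts, a unit that the authors produced with nCounter Advanced Analysis according to the series' design text. Their background correction, their choice of normalization genes and the software version were not given in the sources used here. The table had 768 rows, of which 20, named as panel reference genes, held no value in any sample, and 748 genes had values from -0.57 to 15.23 with 2 decimals. Every column of values was mapped to a sample. In each mouse, low values lay at log2 of whole numbers plus 1 constant for that mouse, for at least 99.6% of the low values tested (tolerance 0.0125 log2, counts up to 40). The constant gave the scaling of each mouse, and with it inferred total counts of 186275 to 694031 per mouse. At these depths a normalized value of 20 stood for 7.27 to 29.7 inferred counts. Symbols were looked up in the RefSeq table, which matched 747 of them and left 1 unmatched.

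Genes were tested when their normalized value reached 20 in at least 4 samples, which kept 619 and left out 129. A linear model with 1 mean per group was fitted to all 23 samples with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend=TRUE). Tests were two-sided, with p adjusted by Benjamini-Hochberg over the 619 genes within a comparison and a threshold of 0.05. The comparisons were each vehicle genotype against wild type, ADPolB against AD on vehicle, urolithin A against vehicle within each genotype, the difference and the mean of these treatment effects, each treated group against wild type, and females against males over all groups with the group means in the model. Correlations between mice used deviations from group means and permutation tests. The comparisons, the filter, the test, the gene lists and the rule for named genes were fixed before the data were examined.

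The rule named, in each comparison, the genes past the threshold (up to 12 rises and 12 falls). Where fewer than 10 passed, it added the 10 genes with the smallest p, said to miss the threshold. It also named the 3 members with the smallest p of each list described, and Mapt, Apoe and Ctsz in every comparison. The rule's other fixed genes, among them Polb, App, Trem2 and Gfap, were not analysed here because they were not among the genes measured. A few genes that the rule names are not reported here. The 24 gene lists covered energy, lipid, amino acid and nucleotide metabolism, lysosome and autophagy, DNA repair and stress, immune signalling, growth signalling and the cell cycle. Of 9 lists of cell type markers, 4 had the 3 tested members required. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. Counts adjusted over the list alone used the same gene tests with Benjamini-Hochberg over the members of 1 list.

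Alternatives were other scalings (each mouse centred on its median, on the 2 reference genes with values, or quantile normalization), no filter and a filter of 50, sex as a covariate, only the groups compared, replicate numbers as a block, limma without a trend or with robust moderation, array weights, ordinary regression per gene with Benjamini-Yekutieli adjustment, and leaving out each mouse in turn. Chosen after seeing the data were leaving out both ADPolB mice with low inferred totals, leaving out Tkt, covariates for the Ttr level and the scaling constant, and fry without Tkt or on median-centred values. The workflow was tested on simulated data with known changes, in which genes varied independently. In 20 simulations of AD against wild-type mice with 200 changed genes, 54.5% of changes of 0.5 log2 and 82.0% of changes of 1 log2 were called. With 20 changed genes, 41.0% and 71.0% were called. In 20 simulations without changes, the largest number of calls was 1. Other tools were statmod 1.5.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.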

Results

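The expression of a panel of mostly metabolic and immune genes was measured in the hippocampus of 23 mice aged 18 months. AD mice carried human APP with the Swedish mutation and human tau with the P301L mutation, among other changes. ADPolB mice also lacked 1 copy of Polb, the gene of DNA polymerase beta, which fills gaps in base excision repair. Urolithin A, a compound that gut bacteria make from ellagitannins of plant foods, was given by oral gavage at 200 mg per kg and day for 5 months, and control mice received vehicle. The replicates in the labels were separate mice in each group: 4 wild-type, 5 AD and 4 ADPolB mice on vehicle, and 5 AD and 5 ADPolB mice on urolithin A. No wild-type mouse on urolithin A was among the samples. There were 11 females and 12 males, 2 and 2 among wild-type mice, 3 and 2 among AD vehicle mice, 1 and 3 among ADPolB vehicle mice, 2 and 3 among treated AD mice, and 3 and 2 among treated ADPolB mice.

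Inferred total counts averaged 529850 ± 58924 (SD, n = 4) in wild-type mice, 531232 ± 36016 (n = 5) in AD vehicle mice and 529254 ± 51751 (n = 4) in ADPolB vehicle mice. Treated AD mice averaged 527488 ± 102743 (n = 5) and treated ADPolB mice 446626 ± 231632 (n = 5). Replicates 3 and 5 of the treated ADPolB group, both females, had the lowest totals, 246455 and 186275, against 426748 to 694031 in the other 21 mice. Values below are log2 of normalized counts, differences are log2 differences with their standard error (SE), and adjusted p-values are from limma over 619 genes. Between 67.5% and 93.2% of genes, depending on the comparison, had a 95% confidence interval that lay within 1 log2 of no difference. In AD against wild-type mice the median interval reached 0.34 to each side.

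The first question was what the AD genotype changed in aged mice without treatment. Pdk1, the kinase that switches off pyruvate dehydrogenase and so holds pyruvate back from the TCA cycle, fell by 0.54 (SE 0.0949, adjusted p = 0.00772), to 0.688 of its wild-type level. It averaged 8.12 ± 0.23 in AD mice (SD, n = 5) and 8.66 ± 0.10 in wild-type mice (n = 4), and was lower in 5 of 5 AD mice. It was the only one of 619 genes to pass in limma, with 57 genes at an unadjusted p under 0.05 (34 higher, 23 lower) where chance gives 30.95. The next 9 genes by p missed the threshold, each with its difference in 5 of 5 mice. Such counts, here and below, are of mice above or below the mean of the other group, not its single mice. For genes picked by their p, they add no separate support. Asns, the asparagine synthetase, differed by -0.44 (SE 0.11, adjusted p = 0.159), and Atf4, the transcription factor of the amino acid stress response, by -0.31 (adjusted p = 0.362). Mapt, the gene of tau, was higher by 0.61 (SE 0.155, adjusted p = 0.159), at 10.41 ± 0.22 against 9.80 ± 0.06. Whether its probe also reads the human tau transgene was not given in the sources used here. Aoc2, an amine oxidase, was higher by 0.61 (adjusted p = 0.243), and Apoc3, an apolipoprotein, by 1.23 (SE 0.368, adjusted p = 0.281). Ndufb4, a subunit of complex I, differed by -0.28 (adjusted p = 0.223) and Fahd1, a mitochondrial hydrolase, by -0.31 (adjusted p = 0.281). The autophagy receptor gene Sqstm1 (-0.18) and the proteasome subunit gene Psma3 (-0.16) both had an adjusted p of 0.362. Apoe, the main lipid carrier of the brain, was higher by 0.21 (SE 0.265, adjusted p = 0.829), in 2 of 5 mice. Ctsz, a lysosomal cathepsin, was higher by 0.37 (SE 0.398, adjusted p = 0.785), in 3 of 5. Without AD vehicle replicate 5 the 2 genes were at -0.0225 and -0.0025.

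By camera at the preset correlation, genes of mitochondrial respiration were low as a group in AD mice, by small amounts. Of 30 tested members, 24 lay below 0 and 6 above, with a median of -0.06 against 0.04 for all genes (camera adjusted p = 0.000194, lower). The adjusted p was 0.409 with an estimated correlation. No gene list passed by fry (smallest adjusted p 0.138), nor by camera after quantile normalization. Of 100 splits of the mice into 2 groups, 33 gave as many list calls. Ndufb4 was the 1 member to pass when adjusted over the list alone. Cox5b (-0.16, adjusted p = 0.362) and Atp5k (-0.16, adjusted p = 0.510), subunits of cytochrome oxidase and ATP synthase, followed. The pyruvate and TCA cycle list was lower too (19 members, 11 below 0, median -0.02, camera adjusted p = 0.0263), with an adjusted p of 0.0940 with an estimated correlation. Without wild-type replicate 1 or 2 or AD vehicle replicate 5 it did not pass. In it Pdk1 passed adjusted over the list alone, and Fh1 (-0.13) and Pdha1 (-0.16) followed. The list was not tested without Pdk1, so its call is not separate from that of Pdk1. It also joins this inhibitor of pyruvate dehydrogenase with genes of the pathway itself. Pdk1 in the hypoxia list and Asns in the amino acid list were the other members to pass adjusted over the list alone. No immune list passed: disease-associated microglia had 11 of 11 members above 0 (median 0.20, camera adjusted p = 0.489), and the microglia and macrophage markers 8 of 8 (median 0.35, adjusted p = 0.391).

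The Pdk1 call depended on how the values were scaled and on single wild-type mice, while its difference was -0.57, -0.54 and -0.58 with median centring, reference gene centring and quantile normalization. Its adjusted p ran from 0.000115 with array weights to 0.494 with only the groups compared, and was 0.0665 without wild-type replicate 1 and 0.0530 without wild-type replicate 4. No gene passed after median centring, reference gene centring or quantile normalization, or by regression per gene with Benjamini-Yekutieli adjustment, and 10 genes passed with array weights.

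**Figure D1:**
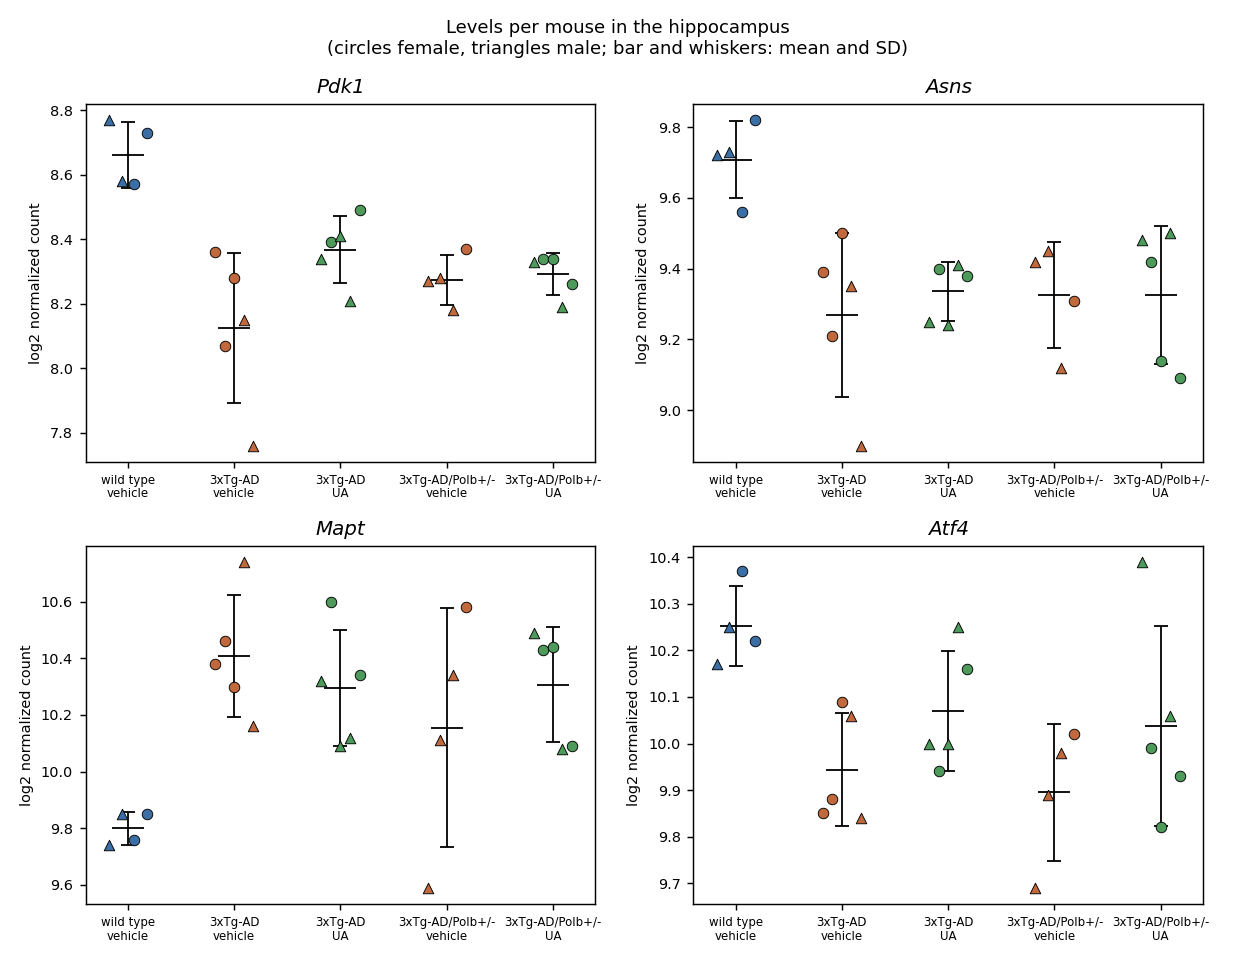
Log2 normalized counts of Pdk1, Asns, Mapt and Atf4 in each of 23 mice, by group; each point is 1 mouse and the bars give the group mean and SD. Pdk1 lay between 8.57 and 8.77 in the 4 wild-type mice and between 7.76 and 8.49 in the 19 transgenic mice.

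The same question was put to ADPolB mice on vehicle. Echs1, an enoyl-CoA hydratase of fatty acid oxidation, was higher than in wild type by 0.41 (SE 0.0917, adjusted p = 0.139), at 8.95 ± 0.13 (n = 4) against 8.54 ± 0.06 (n = 4), and missed the threshold. Pdk1 differed by -0.39 (SE 0.10, adjusted p = 0.157), at 8.28 ± 0.08 against 8.66 ± 0.10. Nme1, a nucleoside diphosphate kinase, differed by -0.60 (SE 0.157), Glul, the glutamine synthetase of astrocytes, by 0.34 (SE 0.0923), Fnip2, a folliculin partner in nutrient sensing, by 0.69 (SE 0.190), and Acap2 by 0.47 (SE 0.126), each with an adjusted p of 0.157. Atf4 (-0.36) and Ddc, which makes dopamine and serotonin (1.10), followed with an adjusted p of 0.198, then Asns (-0.38, adjusted p = 0.228) and Nadk2, the mitochondrial NAD kinase (0.29, adjusted p = 0.230). These 10 differences had their direction in 4 of 4 mice, and Glul was at -0.03 after quantile normalization. Mapt was higher by 0.35 (SE 0.163, adjusted p = 0.352) in 3 of 4 mice, Ctsz by 0.79 (adjusted p = 0.404) and Apoe by 0.48 (adjusted p = 0.451) in 4 of 4.

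In limma 0 of 619 genes passed in ADPolB against wild-type vehicle mice, 81 had an unadjusted p under 0.05 (62 higher, 19 lower), regression per gene gave 0 and array weights gave 132. Adjusted over the list alone, Echs1, Glul, Shmt1 (1.09) and Trp53 (0.57) were higher, and Nme1, Asns, Pdk1, Eno1 (-0.24) and Ldha (-0.41) lower. The last 2 make glycolytic enzymes and passed in the hypoxia list. Mitochondrial respiration was lower (12 of 30 members above and 17 below 0, median -0.03, camera adjusted p = 0.00248), with an adjusted p of 0.587 with an estimated correlation. Its leading members Atp5k (-0.21), Ndufb7 (-0.20) and Cox5b (-0.17) each had an adjusted p of 0.258. Pyruvate and TCA cycle genes were lower (13 of 19 below 0, median -0.07, camera adjusted p = 0.0240), with an adjusted p of 0.0881 with an estimated correlation, although Pdk4 (0.53) and Idh2 (0.41) among its leading members were higher. Neither list passed without ADPolB vehicle replicate 4, nor the TCA cycle list without wild-type replicate 1 or 2. The TCA cycle list holds Pdk1 and was not tested without it. Disease-associated microglia genes missed the threshold (11 of 11 above 0, median 0.49, camera adjusted p = 0.0968). The choroid plexus markers Ttr and Folr1 were higher by 2.25 (SE 2.09) and 1.60 (SE 1.38).

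ADPolB and AD vehicle mice were compared to see what loss of 1 Polb copy added. Slc16a8, a lactate transporter of the retinal pigment epithelium and choroid plexus, was higher by 1.62 (SE 0.555, adjusted p = 0.961) in 4 of 4 ADPolB mice, where Ttr was higher by 2.44 (SE 1.99). Also higher, at the same adjusted p, were Pfkfb1 (0.64), Ndufb4 (0.20), Vegfa (0.44), Psma7 (0.16), Tfrc, the transferrin receptor (0.35), Gpx4, which reduces lipid peroxides (0.19), Cdc20 (1.10) and Hsd11b1 (0.93), and Hras was at -0.27. Mapt differed by -0.25 (SE 0.155), Ctsz by 0.42 (SE 0.398) and Apoe by 0.27 (SE 0.265), with the opposite sign after quantile normalization. Limma called 0 of 619 genes, with 26 at an unadjusted p under 0.05, 0 by regression per gene and 2 with array weights (Echs1 and Gpx4). No list passed with the values as deposited: lysosome and cathepsins (13 of 13 above 0, median 0.33), cytokines (15 of 15, median 0.23) and disease-associated microglia (11 of 11, median 0.33) each had a camera adjusted p of 0.205. After median centring 4 lists passed, and with sex as a covariate 5, both at the preset correlation. The smallest adjusted p with an estimated correlation, with the values as deposited, was 0.827.

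Urolithin A in AD mice was the next question. Pdk1 was higher in treated AD mice by 0.24 (SE 0.0895, adjusted p = 0.932), at 8.37 ± 0.10 (n = 5) against 8.12 ± 0.23 (n = 5). Lepr, the leptin receptor, was higher by 1.20 (SE 0.463), at 6.79 ± 0.50 against 5.59 ± 0.78, and Apoc3 differed by -0.92 (SE 0.347), at 4.23 ± 0.35 against 5.15 ± 0.69. Slc16a7, a neuronal lactate and pyruvate transporter (0.27), Pgk1 of glycolysis (0.22), Lama4 (0.62), Rad51ap1 (0.54) and Cdc20 (1.10) were higher in 5 of 5 treated mice and Pparg, a regulator of lipid storage (0.83), in 4 of 5, and Folh1, which cleaves N-acetylaspartylglutamate, was at -0.53. These genes and Ctsz (0.45, SE 0.375) and Mapt (-0.11, SE 0.146) had an adjusted p of 0.932, and Apoe was at 0.04 (SE 0.250, adjusted p = 0.990), with the opposite sign after each of the 3 other scalings. With limma 0 of 619 genes passed, with 21 at an unadjusted p under 0.05 (19 higher, 2 lower), 0 by regression per gene and 1 with array weights (Naglu, a lysosomal glucosaminidase, 0.78).

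Respiratory genes lay slightly higher in treated AD mice. Of 30 members of mitochondrial respiration 27 were above 0 and 2 below (camera adjusted p = 0.0188). Their median of 0.09 lay close to that of all genes, 0.07. The adjusted p was 0.786 with an estimated correlation. Uqcrq (0.11), Ndufa4 (0.14) and Tfam (0.14) led it, each with an adjusted p of 0.932. The list's direction turned after median centring (adjusted p = 0.969) and reference gene centring (adjusted p = 0.610), which moved the median of all genes by -0.09 and -0.20, and the call was lost without AD vehicle replicate 1, 4 or 5 or treated AD replicate 3. Pyruvate and TCA cycle genes were called higher by fry (adjusted p = 0.0196, 15 of 19 above 0), with Pdk1, Idh3a (0.17) and Mpc1 (0.17) first, but their median of 0.06 lay below that of all genes, 0.07. Camera gave an adjusted p of 0.271, and with median centring the fry call was lost and its direction turned (adjusted p = 0.90). Lysosome (13 of 13 above 0, median 0.21), cytokine (15 of 15, median 0.30) and antigen presentation genes (8 of 9, median 0.47) did not pass, where Ttr was higher by 1.99 (SE 1.87).

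In ADPolB mice Glul was lower with urolithin A by a difference of -0.28 (SE 0.0876, adjusted p = 0.547), at 13.60 ± 0.08 (n = 5) against 13.88 ± 0.16 (n = 4). H2-Eb1, an MHC class II chain, was higher by 1.83 (SE 0.573, adjusted p = 0.547), at 6.64 ± 1.13 against 4.82 ± 0.60, and Tecr, of very-long-chain fatty acid synthesis, by 0.21 (SE 0.0590, adjusted p = 0.421). The corepressor gene Ncor1 (-0.26, adjusted p = 0.421), Braf (-0.27, adjusted p = 0.582), the kynurenine pathway gene Afmid (0.83, adjusted p = 0.629), Acap2 (-0.34), Bcl2 (0.68) and Ranbp2 (-0.20, each adjusted p = 0.642) were also among the genes of smallest p. These 9 had their direction in 5 of 5 treated mice and missed the threshold. Mapt (0.15, SE 0.155, adjusted p = 0.874), Apoe (0.22, SE 0.265, adjusted p = 0.900) and Ctsz (0.18, SE 0.398, adjusted p = 0.921) were each higher in 3 of 5, and Ctsz had the opposite sign without both treated mice of low total counts. In limma 0 of 619 genes passed, with 40 at an unadjusted p under 0.05 (15 higher, 25 lower) and 0 by regression per gene and with array weights.

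Genes of PI3K-AKT and MAPK signalling were lower in treated ADPolB mice (18 of 25 below 0, median -0.07, camera adjusted p = 0.00696), with an adjusted p of 0.802 with an estimated correlation. Braf was at -0.27 (adjusted p = 0.582). No list passed without both treated mice of low total counts, nor with the scaling constant as a covariate. H2-Eb1, Tecr and Afmid (higher) and Glul (lower) passed adjusted over the list alone in their lists. Antigen presentation missed the threshold (8 of 9 above 0, median 0.39, camera adjusted p = 0.0772), with H2-Aa at 1.90, where Ttr was higher by 1.51 (SE 1.99).

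The difference between the treatment effects of the genotypes was tested directly, and no gene passed. Slc16a7 (-0.49, SE 0.151), Tfrc (-0.52), Psma7 (-0.24), Nat8l, the synthase of N-acetylaspartate (-0.60), Adcy2 (-0.65), Ranbp2 (-0.27), Pik3r2 (-0.33), Ncor1 (-0.26) and Rimklb (0.68) were among the first by p, each with an adjusted p of 0.883. Mapt (0.27, SE 0.213), Apoe (0.18, SE 0.364) and Ctsz (-0.27, SE 0.546) each had an adjusted p of 0.990. Limma called 0 of 619 genes, with 31 at an unadjusted p under 0.05 and 0 by regression per gene and with array weights, and no list passed.

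Over both genotypes no gene passed for the mean effect of urolithin A. H2-Eb1 was at 1.35 (SE 0.394), H2-Aa, another MHC class II chain, at 1.61 (SE 0.510), Lepr at 1.08 (SE 0.338) and Tecr at 0.13 (SE 0.0405), each with an adjusted p of 0.726. Apoc2, a cofactor of lipoprotein lipase (0.85), Slc6a12, a betaine and GABA transporter (0.70), Eno1 of glycolysis (0.14), Glul (-0.17), Ncor1 (-0.13) and Smad4 (-0.19) followed with an adjusted p of 0.740. Tecr and Eno1 had the opposite sign after reference gene centring, as had Mapt and Apoe. Ctsz was at 0.31 (adjusted p = 0.792), Apoe at 0.13 (adjusted p = 0.877) and Mapt at 0.02 (SE 0.106, adjusted p = 0.956). With limma 0 of 619 genes passed, with 34 at an unadjusted p under 0.05 and 0 by regression per gene and with array weights. Antigen presentation was higher as a list (8 of 9 above 0, median 0.41, camera adjusted p = 0.0415), with an adjusted p of 0.781 with an estimated correlation; H2-Eb1 and H2-Aa passed adjusted over the list alone, and H2-T23 was at 0.60. PI3K-AKT and MAPK signalling was lower (15 of 25 below 0, median -0.02, camera adjusted p = 0.0208), again with an adjusted p of 0.781 with an estimated correlation, with Braf at -0.12 and Pdpk1 at -0.15 among its leading members. Fry called the pyruvate and TCA cycle list higher (16 of 19 above 0, adjusted p = 0.0432), but not with median centring, where its direction turned (adjusted p = 0.938). No list passed camera without both treated ADPolB mice of low total counts, nor with Ttr or the scaling constant as a covariate; Ttr itself was higher by 1.75 (SE 1.37). Antigen presentation was lost without any of 11 single mice and PI3K-AKT and MAPK signalling without any of 5.

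Whether urolithin A moved genes back toward wild type was examined across all 619 genes, which are not independent replicates. The difference of AD vehicle from wild-type mice and the difference of treated from vehicle AD mice had a correlation of -0.32. The shared vehicle group makes this negative by chance: 100 simulations of unchanged groups gave a mean of -0.46 (-0.76 to -0.03). With the vehicle mice split between both differences the mean over 20 splits was 0.11 (-0.26 to 0.44). In ADPolB mice the correlation was -0.01, the simulated mean -0.52 (-0.86 to -0.03) and the mean over 6 splits 0.23 (-0.07 to 0.51). With all mice, neither genotype had a correlation more negative than the simulated mean. Leaving out 1 mouse gave -0.48 to -0.0253 in AD and -0.20 to 0.15 in ADPolB mice, and leaving out both mice of low total counts gave -0.32 in ADPolB mice.

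Treated mice were also compared with wild type. In treated ADPolB mice Stat5a, a cytokine signal transducer, was higher by 1.11 (SE 0.268), at 5.41 ± 0.38 (n = 5) against 4.30 ± 0.38 (n = 4), and Pdk1 differed by -0.37 (SE 0.0949), at 8.29 ± 0.07. The natriuretic peptide receptor gene Npr2 (0.48), Fgf1 (0.70), Ddc (1.09), Idh2 (0.61), Ern1, a sensor of unfolded protein (0.59), Ctsl, a lysosomal cathepsin (0.58), Mapt (0.51), Asns (-0.38) and Srr, the serine racemase (-0.37), shared their adjusted p of 0.157. Each of these 11 genes had its direction in 5 of 5 mice, as did Apoe, higher by 0.70 (SE 0.265, adjusted p = 0.177), and Ctsz, higher by 0.96 (SE 0.398, adjusted p = 0.202). In limma 0 of 619 genes passed, with 136 at an unadjusted p under 0.05 (106 higher, 30 lower), 0 by regression per gene and 182 with array weights. The 136 became 42 without both mice of low total counts, 63 with the scaling constant and 66 with Ttr as a covariate, each with 0 genes past the threshold. Without wild-type replicate 3, 13 genes passed, and without treated ADPolB replicate 2, 10 genes.

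Lists of microglial and lysosomal genes were higher in treated ADPolB mice. Disease-associated microglia genes (11 of 11 above 0, median 0.86, camera adjusted p = 0.00417), lysosome and cathepsins (13 of 13, median 0.58, adjusted p = 0.00907) and cytokines, NF-kB and TLR signalling (15 of 15, median 0.84, adjusted p = 0.00919) were higher, and mitochondrial respiration lower (21 of 30 below 0, median -0.05, adjusted p = 0.00185). For these 4 lists the adjusted p was 0.619 with an estimated correlation. Ctsl passed adjusted over the list alone, and Cd63 (0.91) in the lysosome list and Cd14 (1.27), Nfkb1 (0.57) and Nfkb2 (0.81) among cytokines came next. Antigen presentation did not pass (median 1.02, 6 of 9 above 0, adjusted p = 0.279), with H2-K1 at 1.21 and H2-D1 at 1.33. The microglia and macrophage markers were at 0.93 (8 of 8 above 0, adjusted p = 0.0918), Ttr at 3.75 (SE 1.99) and Folr1 at 2.77 (SE 1.31). Without both mice of low total counts the lysosome and cytokine lists missed the threshold (median 0.49, adjusted p = 0.0812, and median 0.51, adjusted p = 0.0596), and disease-associated microglia passed (median 0.59, adjusted p = 0.0151).

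Treated AD mice differed from wild type by 0.61 in Cacna1a, a neuronal calcium channel (SE 0.159, adjusted p = 0.446), at 8.89 ± 0.35 (n = 5) against 8.28 ± 0.07 (n = 4), and by 0.76 in Rps6ka1, a kinase downstream of MAPK (SE 0.214). Asns (-0.37), Cox14 (0.25), Mapt (0.49), Pdk1 (-0.29), Rad51ap1 (0.71) and Slc3a1 (1.02) had the same adjusted p, and Echs1 (0.26) and Stat6 (0.83) one of 0.452, all in 5 of 5 mice. Ctsz was at 0.82 (adjusted p = 0.529) and Apoe at 0.25 (adjusted p = 0.693). Limma called 0 of 619 genes, with 57 at an unadjusted p under 0.05 (52 higher, 5 lower), 0 by regression per gene and 92 with array weights. No list passed camera. The pentose phosphate pathway, which makes NADPH, passed by fry (7 of 7 above 0, median 0.28, adjusted p = 0.0169; camera adjusted p = 0.139), with Pgd at 0.21 and Rpia at 0.29. Its member Tkt was at 2.74 because wild-type replicate 1 held 0.00, against 10.38 to 10.92 in the other mice. Whether 0.00 was a measurement or a missing value was not given in the sources used here. Without Tkt the list passed by fry (6 of 6 above 0, median 0.25, adjusted p = 0.0292), and with median centring it did not (adjusted p = 0.134). Disease-associated microglia (11 of 11 above 0, median 0.51) and cytokines (15 of 15, median 0.47) each had a camera adjusted p of 0.139, and after median centring both passed, with mitochondrial respiration and the TCA cycle lower. With an estimated correlation no list passed with the values as deposited (smallest adjusted p 0.589).

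Females and males were compared over all groups, since the groups differed in their sex ratio. H2-Aa was higher in females by 1.52 (SE 0.352, adjusted p = 0.201), at 7.84 ± 1.40 (n = 11) against 6.33 ± 0.94 (n = 12), and H2-Eb1 by 1.12 (SE 0.283, adjusted p = 0.240), each in 9 of 11 females, and both missed the threshold. Tlr7, an X-linked sensor of RNA (0.75, adjusted p = 0.362), Fcgr4, an antibody receptor (0.89, adjusted p = 0.574), Xdh (0.52), H2-T23 (0.63), Ccnd1 (0.41) and Ccl5 (1.13) followed, with Braf (-0.14) lower, the last 5 at an adjusted p of 0.584. Apoe was at 0.28 (adjusted p = 0.689), Ctsz at 0.38 (adjusted p = 0.70) and Mapt at 0.14 (adjusted p = 0.704). With limma 0 of 619 genes passed, with 48 at an unadjusted p under 0.05 (31 higher, 17 lower), 0 by regression per gene and 32 with array weights; without AD vehicle replicate 5, 28 passed, all higher in females.

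Immune gene groups were higher in females. Antigen presentation had 9 of 9 members above 0 (median 0.63, camera adjusted p = 1.7e-06; adjusted p = 0.408 with an estimated correlation), and H2-K1, H2-T23, H2-Aa, H2-Eb1 and Psmb10 passed adjusted over the list alone. Lysosome and cathepsins (13 of 13, median 0.29), cytokines (13 of 15, median 0.41) and disease-associated microglia (11 of 11, median 0.30) each had a camera adjusted p of 0.00206 and an adjusted p of 0.467 with an estimated correlation. Tlr7 passed adjusted over the cytokine list alone, and Ccnd1 adjusted over the list alone in the p53 and cell cycle lists. Markers of microglia and macrophages (8 of 8, median 0.37, camera adjusted p = 0.0353) and of T and NK cells (7 of 7, median 0.39, adjusted p = 0.0176), among them Cd3g (0.60) and Nkg7 (0.92), were higher, both with an adjusted p of 0.303 with an estimated correlation. Of 18 measured T and NK cell markers, only 7 reached the filter. The mice of low total counts, both females, had the highest mean levels of the genes left out by the filter (3.85 and 3.86). The marker lists were not tested without these mice. Without them 5 gene lists passed camera at the preset correlation, 4 of them higher in females. AMPK and mTOR signalling (13 of 19 below 0, median -0.05, adjusted p = 0.0104) and PI3K-AKT and MAPK signalling (20 of 25 below 0, median -0.06, adjusted p = 0.00349) were lower, both with an adjusted p of 0.436 with an estimated correlation.

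Ttr, the transthyretin that the choroid plexus secretes, differed more among mice of 1 group than between groups. It averaged 7.55 ± 3.51 (n = 4) in wild-type mice, 7.36 ± 2.24 (n = 5) in AD vehicle and 9.80 ± 2.84 (n = 4) in ADPolB vehicle mice, and 9.35 ± 3.98 (n = 5) and 11.30 ± 3.14 (n = 5) in treated AD and ADPolB mice. Over 23 mice its deviation from the group mean followed that of Folr1, a folate receptor of the same tissue (r = 0.977, rho = 0.977, permutation p = 1e-05 for both, the smallest possible, adjusted 1.3e-05 over 4 relations, and r = 0.979 without the 2 mice farthest from the median), and that of Slc16a8 (r = 0.832, rho = 0.866, permutation p = 1e-05 for both, adjusted 1.3e-05, and r = 0.842 without 2 mice). The mean of the lysosome list followed that of the microglia markers outside it (r = 0.921, rho = 0.932, permutation p = 1e-05 for both, adjusted 1.3e-05, and r = 0.870 without 2 mice).

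**Figure D2:**
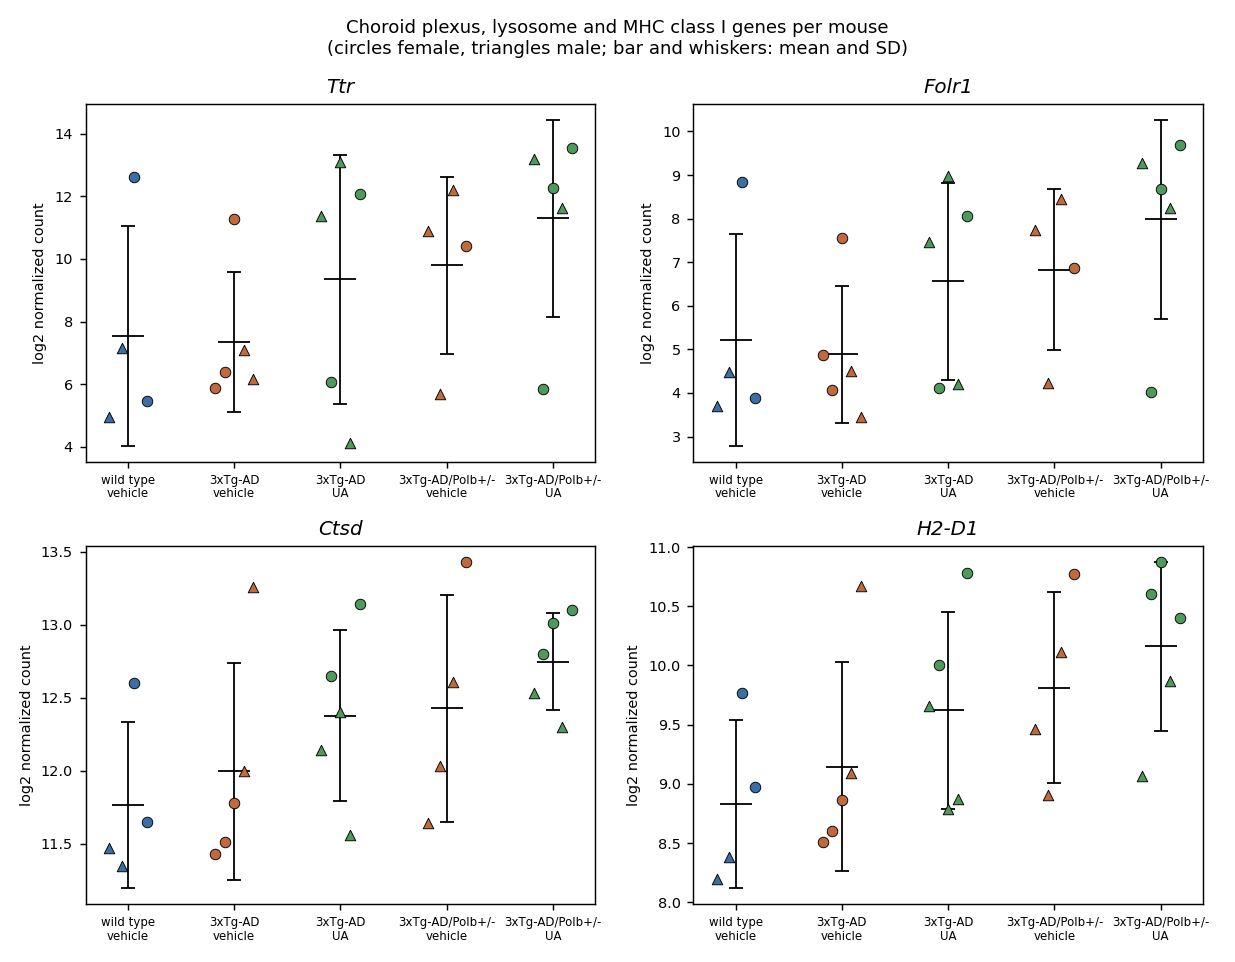
Log2 normalized counts of Ttr, Folr1, Ctsd and H2-D1 in each of 23 mice, by group; each point is 1 mouse and the bars give the group mean and SD. Ttr ran from 4.95 to 12.62 in wild-type mice and from 5.85 to 13.55 in treated ADPolB mice.

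Of the 24 gene lists, 16 passed camera in none of the 10 comparisons, with medians between -0.30 and 0.50 and a smallest adjusted p of 0.0694. Their smallest camera adjusted p was 0.0694 for glycolysis and lactate, 0.386 for fatty acid oxidation, 0.323 for fatty acid and sterol synthesis, 0.139 for the pentose phosphate pathway, 0.271 for amino acid and one-carbon metabolism, 0.290 for glutamine and glutamate metabolism and 0.371 for nucleotide metabolism. It was 0.214 for amino acid and glucose transporters, 0.147 for autophagy and mitophagy, 0.418 for base excision and other DNA repair, 0.323 for p53 and senescence, 0.147 for cGAS-STING and interferon, 0.245 for NRF2 and reactive oxygen response, 0.165 for hypoxia, 0.271 for kynurenine and NAD and 0.160 for the cell cycle. Among marker lists, neurons (smallest adjusted p 0.182) and endothelial cells and pericytes (0.0788) did not pass either. Of the 5 marker lists with fewer than 3 tested genes, astrocytes had Glul and the choroid plexus had Ttr and Folr1, given above, and B cells had no tested gene. The oligodendrocyte gene Aspa was higher than in wild type in all 4 transgenic groups and missed the threshold in each. The difference was 0.87 (SE 0.431, adjusted p = 0.518) in AD and 1.195 (SE 0.454, adjusted p = 0.348) in ADPolB vehicle mice. It was 0.90 (SE 0.431, adjusted p = 0.528) in treated AD and 1.14 (SE 0.431, adjusted p = 0.177) in treated ADPolB mice. The granulocyte genes Mpo and Csf3r were at 0.41 (SE 0.456) and 0.59 (SE 0.447) in treated ADPolB mice.

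**Figure D3:**
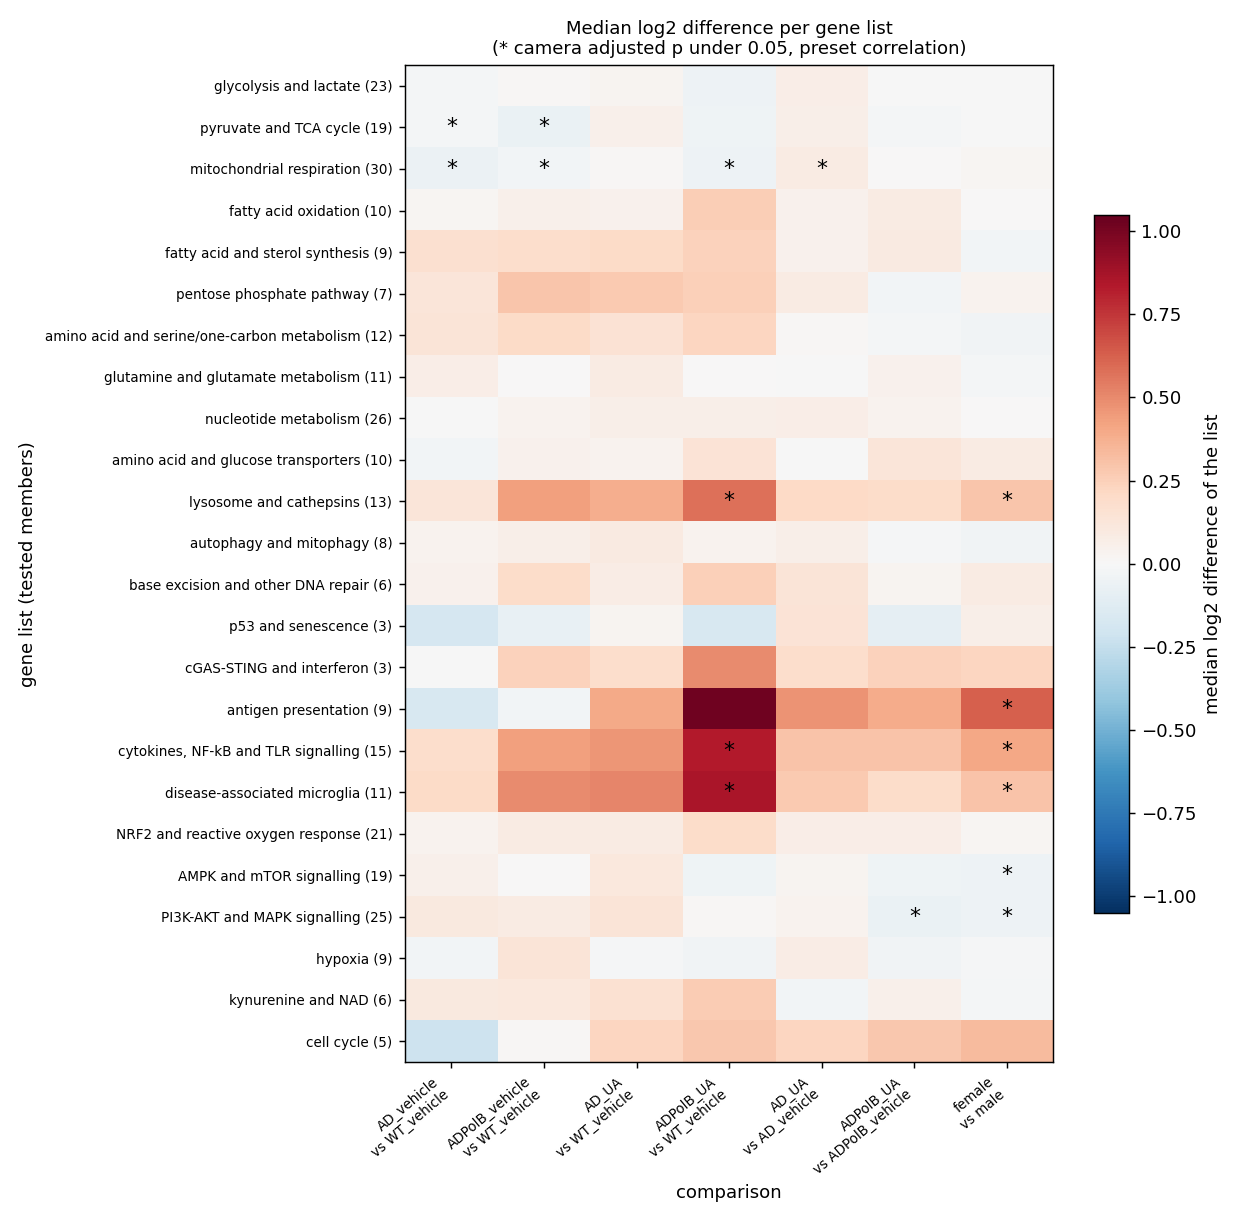
Median log2 difference of each of 24 gene lists (lines, tested members in brackets) in 7 comparisons (columns), on a colour scale from blue (lower) to red (higher); a star marks a camera adjusted p under 0.05 at the preset correlation. The highest median is that of antigen presentation in treated ADPolB against wild-type mice, 1.02.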

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

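The relation of Ttr to Folr1 was tested only after the spread of both genes had been seen. A mouse is given here when, for a named gene or a measure of its sample, its gap to the nearest mouse of its group was large against the range of the group (Dixon's ratio, the value in brackets). There were 32 such cases in 365 tests of groups, where chance gives 18.25.

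Replicate 5 of the AD vehicle group, a male, lay above its group in Apoe (0.848; 13.99 against 12.74 to 12.93), Ctsz (0.751; 10.47 against 8.34 to 8.87), Bcl2 (0.835), Ccl5 (0.716), Ddc (0.732), Echs1 (0.733), Fgf1 (0.862), Hras (0.744), Rps6ka1 (0.80) and Smad4 (0.727). Its array weight was 0.145, against 0.494 to 3.22 in the other 22 mice.

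Wild-type replicate 3 lay above its group in Apoe (0.927; 13.15 against 12.74 to 12.77), Ctsl (0.868), Ctsz (0.838; 9.55 against 8.19 to 8.41), Lepr (0.838), Stat6 (0.893) and Folr1 (0.848; 8.83 against 3.69 to 4.47). Wild-type replicate 4 lay below in Hsd11b1 (0.923; 6.19 against 7.98 to 8.13) and above in Psma3 (0.842), and wild-type replicate 1 below in Pgk1 (0.929). Treated AD replicate 2 lay below in Ddc (0.833), and treated AD replicate 4 below in Nadk2 (0.941) and Psma3 (0.727). ADPolB vehicle replicate 1 lay above in Lama4 (0.830), Tfrc (0.882) and Vegfa (0.851), and replicate 4 above in Tlr7 (0.898) and in the log2 scaling constant (0.886; 0.17 against -0.18 to -0.14). Treated ADPolB replicate 5 lay below in Hsd11b1 (0.804), and treated ADPolB replicate 2 above in Ncor1 (0.75).

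Ttr and Folr1 set single mice apart in 3 groups. AD vehicle replicate 3 was high in Ttr (0.776; 11.28 against 5.87 to 7.08), wild-type replicate 3 high in Folr1, and treated ADPolB replicate 2 low in Ttr (0.752; 5.85 against 11.64 to 13.55) and Folr1 (0.744; 4.03 against 8.24 to 9.69). Both genes rose and fell together from mouse to mouse (r = 0.977 over 23 mice, deviations from group means), so varying amounts of choroid plexus in the dissected tissue are a candidate explanation. A share of it that comes from the scaling stays open, since Ttr and the log2 scaling constant had r = 0.331 (permutation p = 0.13, rho = 0.334, permutation p = 0.12, r = 0.375 without the 2 mice farthest from the median). No biological explanation of the spread within groups was tested, and whether genotype or urolithin A changes choroid plexus genes stays open as well.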

How the results depend on the processing

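The settings chosen after seeing the data were those without both mice of low total counts, without Tkt, and with Ttr or the scaling constant as a covariate, and fry without Tkt or with median centring. The planned pseudocount of 10 and the tests for counts were not run, because the values were log2 of normalized counts; the fit with only the groups compared was not run for the difference and the mean of the treatment effects or the sex comparison. The array weights gave a warning in 1 split that their tolerance was not reached. Unless a value shows otherwise, the cause of each change was not tested. Depth limits genes near the filter, where a normalized value of 20 stood for as few as 7.27 counts.

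Genes past the threshold. In AD against wild-type vehicle mice the count of 1 became 0 with median centring, reference gene centring, quantile normalization, only the groups compared and regression per gene, and 10 with array weights (Apoc3, Asns, Brcc3, Col4a1, Cox5b, Fahd1, Mapt, Ndufb4, Pdk1 and Sqstm1). Counts of 0 became, with array weights, 132 in ADPolB and 182 in treated ADPolB against wild-type mice, 92 in treated AD against wild-type mice, 2 in ADPolB against AD, 1 for urolithin A in AD mice and 32 for sex. Leaving out 1 mouse gave 0 to 2 in AD against wild type (0 without wild-type replicate 1 or 4, 2 without ADPolB vehicle replicate 1), 0 to 6 in ADPolB against wild type (6 without AD vehicle replicate 5), 0 to 13 in treated ADPolB against wild type (13 without wild-type replicate 3, 10 without treated ADPolB replicate 2), 0 to 28 for sex (28 without AD vehicle replicate 5) and 0 in the other planned comparisons. For the mean of all transgenic groups against wild type it gave 0 to 4 (4 without AD vehicle replicate 5).

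With the replicate block, 1 gene (Echs1) passed in ADPolB against wild-type mice, lists numbered 1 in AD against wild type, 4 in ADPolB against AD, 0 for urolithin A in AD mice and 0 for the mean effect, and Ctsz for urolithin A in ADPolB mice was at -0.040. For all transgenic groups against wild type 0 genes passed with it, where 1 had, and 1 list where 3 had. The mice of 1 number were different animals. Over 43 pairs of equal number r ran from -0.39 to 0.55, with a median of 0.17 and 27 pairs over 0.1. Of 23 mice, 6 were closest to one of their own number. Deviations from group means cancel within a group, so pairs from different groups have on average no covariance. The median of 0.17 thus leaves open a factor shared by mice of equal number. Pairs of unequal number were not summarised for comparison.

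Gene lists called. In AD against wild type, 2 became 0 with an estimated correlation, fry and quantile normalization and 1 with median and reference gene centring. In ADPolB against wild type, 2 became 0 with an estimated correlation and fry, 4 with median centring, 5 with reference gene centring and 4 with sex as a covariate. In ADPolB against AD, 0 became 4 with median and reference gene centring and 5 with sex. For urolithin A in AD mice, 1 became 0 with an estimated correlation and quantile normalization, 5 with median and reference gene centring and 2 with sex; in ADPolB mice, 1 became 0 with an estimated correlation, fry, the scaling constant and without both mice of low total counts, 2 with median and 5 with reference gene centring. For the mean effect, 2 became 0 with an estimated correlation, Ttr, the scaling constant and without both mice, 1 with fry and without the filter, 6 with median centring, 7 with reference gene centring and 4 with quantile normalization. In treated AD against wild type, 0 became 1 with fry and quantile normalization, 4 with median and 5 with reference gene centring. In treated ADPolB against wild type, 4 became 0 with an estimated correlation and fry, 8 with reference gene centring, and 2 with the scaling constant and without both mice. For sex, 6 became 0 with an estimated correlation and fry. By fry with median centring, lists numbered 1 in ADPolB against wild type (the pentose phosphate pathway, adjusted p = 0.0369) and for sex (antigen presentation, adjusted p = 0.0276) and 0 in the other planned comparisons; leaving out Tkt changed no fry count. For all transgenic groups against wild type, 3 became 0 with an estimated correlation, 1 with fry (the pentose phosphate pathway, adjusted p = 0.0143), 5 with median and reference gene centring, 4 with sex, 2 with Ttr, the scaling constant and without both mice, and 1 to 6 with 1 mouse left out. Leaving out 1 mouse gave 1 to 2 lists in AD and 0 to 6 in ADPolB against wild type, 0 to 4 in ADPolB against AD, 0 to 4 and 0 to 5 for urolithin A in AD and ADPolB mice, 0 to 2 for the difference, 0 to 6 for the mean, 0 to 2 and 4 to 7 for treated AD and ADPolB against wild type, and 5 to 6 for sex.

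Of the list calls, mitochondrial respiration in AD against wild type, the 4 of treated ADPolB against wild type and 5 of the 6 of sex passed without any 1 mouse. The TCA cycle call was lost in AD against wild type without wild-type replicate 1 or 2 or AD vehicle replicate 5, and in ADPolB against wild type without wild-type replicate 1 or 2 or ADPolB vehicle replicate 4, as was mitochondrial respiration there without the last. For urolithin A in AD mice mitochondrial respiration was lost without AD vehicle replicate 1, 4 or 5 or treated AD replicate 3. Without treated ADPolB replicate 5, PI3K-AKT and MAPK signalling in ADPolB mice and AMPK and mTOR signalling for sex were lost. For the mean effect, antigen presentation was lost without 11 and PI3K-AKT and MAPK signalling without 5 of the 23 mice, each taken alone.

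Scaling moved the median of all genes by more than 0.1 log2 in several comparisons: median centring by -0.12 in both treated groups against wild type, reference gene centring by -0.14 to -0.29 in all but AD against wild type and the difference of effects, and quantile normalization by -0.12 to -0.17 in ADPolB and the treated groups against wild type. The direction turned for Glul in ADPolB against wild type (-0.030 with quantile normalization) and Apoe in ADPolB against AD (-0.029 with quantile normalization). For urolithin A in AD mice, Apoe was at -0.058 with median centring, -0.16 with reference gene centring, -0.24 with quantile normalization and -0.015 with Ttr, and mitochondrial respiration turned with median (adjusted p = 0.969) and reference gene centring (adjusted p = 0.610). In ADPolB mice Ctsz was at -0.026 without both mice and -0.049 with the scaling constant. Apoe was at -0.21 with array weights for the difference. For the mean effect, Mapt was at -0.053 with median centring, -0.15 with reference gene centring and -0.0098 with array weights, Tecr at -0.039, Eno1 at -0.030 and Apoe at -0.046 with reference gene centring, and Apoe at -0.058 with quantile normalization.

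Leaving out 1 mouse also turned the direction of Apoe in AD against wild type (-0.0225 to 0.31), for urolithin A in AD mice (-0.09 to 0.27) and for the difference (-0.051 to 0.38), of Ctsz in AD against wild type (-0.0025 to 0.68), for urolithin A in ADPolB mice (-0.0653 to 0.49) and for the difference (-0.65 to 0.0447), and of Mapt for urolithin A in ADPolB mice (-0.0373 to 0.29) and for the mean (-0.0757 to 0.0893). Of the values of named genes with 1 mouse left out, 16 turned, 3211 kept direction and side of the threshold, 31 passed newly and 8 no longer passed; with array weights these were 2, 75, 63 and 0. The correlation of genotype and treatment effects was 0.11 in AD and 0.23 in ADPolB mice with vehicle mice split, -0.32 in ADPolB mice without both mice of low total counts, and -0.48 to -0.0253 and -0.20 to 0.15 with 1 mouse left out.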

Other observations

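The comparison of all 4 transgenic groups with wild type, the tests of Pdk1 and the tests that leave out both mice of low total counts were chosen after the data had been seen.

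Against the 4 wild-type mice, the mean of the 4 transgenic groups was lower in Pdk1 by a difference of -0.40 (SE 0.0779, adjusted p = 0.0290, lower in 19 of 19 mice), the 1 gene past the threshold, with 103 at an unadjusted p under 0.05 (80 higher, 23 lower). The count was 189 (150 higher) with array weights, and 0 with median centring, reference gene centring, quantile normalization and regression per gene and without both mice of low total counts. Its adjusted p ran up to 0.246 in other settings and to 0.318 without wild-type replicate 1, and it passed without 17 of the 23 mice, each taken alone. Asns (-0.39, SE 0.0899, adjusted p = 0.0822), Echs1 (0.29, adjusted p = 0.126), Fnip2 (0.56, adjusted p = 0.139) and Cox5b, of cytochrome oxidase (-0.17, adjusted p = 0.146), had their direction in 19 of 19 mice, and Mapt (0.49, adjusted p = 0.139), Atf7 (0.41), Aoc2 (0.47) and Atf4 (-0.27, adjusted p = 0.158) in 18. Pdk1 and Asns lay above, and Echs1 and Fnip2 below, every transgenic mouse in all 4 wild-type mice. Chance gives such a separation for 0.0226% of genes, or 0.140 of 619. The gaps were narrow. The highest wild-type and lowest transgenic mouse were at 8.6 and 8.61 in Echs1 and at 7 and 7.08 in Fnip2. The lowest wild-type and highest transgenic mouse were at 8.57 and 8.49 in Pdk1 and at 9.56 and 9.5 in Asns. Separation was examined only with the values as deposited, in a comparison chosen after the data had been seen, so chance is not excluded. Among lists, mitochondrial respiration (camera adjusted p = 0.000453; adjusted p = 0.453 with an estimated correlation) and the TCA cycle (0.0369; 0.120; not passed without wild-type replicate 1 or 2) were lower, and disease-associated microglia higher (0.0428; 0.914; not passed without any 1 of 10 mice). None of the 3 passed by fry (smallest adjusted p 0.290). The TCA cycle list, which holds Pdk1, was not tested without that gene.

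With array weights, which give less weight to mice that vary more, ADPolB vehicle mice differed from wild type in 132 genes (112 higher), treated ADPolB mice in 182 (152 higher) and treated AD mice in 92 (84 higher). Among wild-type mice the 2 males had array weights of 2.94 and 3.22 and the 2 females 0.575 and 0.706. The weighted wild-type mean thus rested mostly on 2 male mice. Sex is therefore not separated from genotype and treatment in the counts against wild type with array weights. Females differed from males in 32 genes, 31 of them higher. Without AD vehicle replicate 5, the 28 genes higher in females included H2-Aa, H2-Eb1, H2-D1, H2-K1, Cd68, Ctss, Tlr2, Tlr4, Ptprc, Ctsd and Hexa.

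Pdk1 was the only gene past the threshold in AD against wild-type mice. Its difference was at least 99.6% as large under each other scaling. In this comparison median centring, reference gene centring and quantile normalization moved the median of all genes by only -0.0265, 0.002 and -0.0568. A difference of -0.54 could hardly shrink under such shifts, so this test could not show the deposited scaling as its source. The Pdk1 call ended under each other scaling because the spread grew. The difference was -0.54 (SE 0.0949) as deposited and -0.57 (SE 0.125, adjusted p = 0.108) with median centring. It was -0.54 (SE 0.168, adjusted p = 0.433) with reference gene centring and -0.58 (SE 0.129, adjusted p = 0.125) with quantile normalization. A difference in genetic background between the colonies cannot be told apart from an effect of the transgenes, since 19 of 19 transgenic mice lay below the lowest wild-type mouse, which both predict, and the labels give 1 background for every mouse. For the count of genes in AD against wild-type mice, 2 of 100 splits, the real one included, gave as many. The real split gave 1 and the others at most 1. Many counts were tested by splits without adjustment over these tests, so chance is not excluded. A single call was also the largest number in 20 simulations without changes, and the Pdk1 call was lost without wild-type replicate 1 or 4. For all transgenic groups, a comparison chosen after the data had been seen, 4 of 100 splits gave as many. There the real split gave 1 and the others up to 5.

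Lysosome, cytokine and disease-associated microglia genes were higher in treated ADPolB than in wild-type mice by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.619 for each list). With sex as a covariate at least 94.2% of each list's median remained. The groups had nearly equal sex ratios, 3 females and 2 males in treated ADPolB and 2 and 2 in wild-type mice. This share was therefore largely fixed in advance and is no separate test. The near-equal ratio itself leaves little room for the sex ratio as the source of the difference with all mice. Low depth stays open. Without both mice of low total counts at least 60.9% of each median remained, and the lysosome and cytokine lists missed the threshold. Both of these mice were female, and the same lists were higher in females by camera at the preset correlation. Leaving out these mice thus changed depth and the sex ratio together, and their shares cannot be told apart here. The mean log2 value of the 129 genes left out by the filter, a measure of background, was 3.42 ± 0.40 (n = 5) in treated ADPolB and 3.00 ± 0.14 (n = 4) in wild-type mice (exact permutation p = 0.127, adjusted 0.254), and the 2 mice of low total counts, at 3.85 and 3.86, lay above the other 21, at 2.86 to 3.56. Chance cannot be excluded for the number of lists, which 20 of 100 splits reached (4 in the real split, up to 8 in the others), so an effect of genotype and treatment may be part of the difference but is not separated from these.

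A hypothesis was that Asns and Atf4 were low because the amino acid response of ATF4 was low. Of 11 other known targets, among them Psat1, Phgdh, Shmt2, Slc7a11 and Slc7a5, 9 were higher and 2 lower in transgenic mice, and their median lay -0.024 from that of all genes (camera p = 0.699, and p = 0.769 with an estimated correlation). The test gave no sign of a lower response and, with a median this close to that of all genes, does not exclude a small one.

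Other splits of the mice tested the remaining counts. For genes at an unadjusted p under 0.05, as many were given by 3 of 35 splits in ADPolB against wild-type vehicle mice (81 real, up to 143 in the others), 60 of 100 in ADPolB against AD (26; 153), 62 for urolithin A in AD mice (21; 130), 32 in ADPolB mice (40; 82), 41 for the difference of these effects (31; 131), 41 for their mean (34; 144), 8 in treated AD (57; 117) and 5 in treated ADPolB against wild-type mice (136; 168), and 16 for sex (48; 125). Chance cannot be excluded for any of these. Splits with several times the real count, such as 153 against 26, point to a structure among the mice; whether single mice or genes that vary together made it was not tested. For gene lists, as many were given by 33 of 100 splits in AD (2; 5) and 16 of 35 in ADPolB against wild-type mice (2; 6). The number was 56 for urolithin A in AD (1; 6), 62 in ADPolB mice (1; 7) and 39 for the mean (2; 7). It was 23 for all transgenic groups (3; 8), and chance cannot be excluded for any of these. For sex it was 3 (6; 7), a small share, but the split tests were not adjusted for their number. In ADPolB against AD, for the difference and in treated AD against wild-type mice the real count of lists was 0, which every split reaches, so the splits tested nothing there. With array weights, 3 of 100 splits gave as many genes in AD against wild-type mice (10 real, up to 11 in the others). The number was 2 of 100 for treated ADPolB against wild-type mice (182 and 191) and 2 for sex (32 and 39). It was 3 of 35 for ADPolB (132 and 163) and 7 of 100 for treated AD against wild-type mice (92 and 142). Array-weight counts of the other comparisons were not tested by splits. Without adjustment over the split tests, chance is not excluded for any of these counts.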
